A study of Escherichia coli K-12 with 11 samples.

How the data were processed

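The samples were 11 libraries of total RNA from Escherichia coli K-12 substrain MC4100, grown in LB with 0.1% ampicillin at 37 °C. ReACT-seq places an azide on RNA at the methylthio group of 2-methylthio-N6-isopentenyladenosine (ms2i6A), through which tagged fragments can be bound to biotin and enriched. Per the labels, the RNA was fragmented, the biotin reagent was used in the 4 treated libraries, and it was not used in the 4 control libraries. The labels do not settle whether the controls were left without labelling or only without enrichment. A further 3 libraries, 1 each with Superscript III (RTase_SS), HIV reverse transcriptase (RTase_HIV-RT) and MMuLV reverse transcriptase (RTase_MMuLV), were labelled but not enriched. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

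Trim Galore 0.6.7, Bowtie2 2.2.5 and MACS2 are named in the submitters' processing notes, without role or order. How stops were counted, which tRNA reference was used and how reads were filtered is not given in the sources used here. Each of the 11 deposited tables gives, per the file headers, the coverage of a position as a raw count of reads, the coverage by reads that stop there (a signal of whole numbers), and the stop rate in percent. The deposited stop rate in percent equalled stops over coverage to within 0.005 percentage points. The tables list 9 tRNA sequences, all from tRNAs known to carry ms2i6A. Peaks came as 2 deposited lists, 1 for treated replicates 1 and 2 and 1 for treated replicates 3 and 4. They held coordinates on the MG1655 chromosome and no score, and were read as combined calls per pair of replicates.

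Of 709 rows per table, 8 were left out. They closed a tRNA, were listed under its name, and had as many stops as reads. Their read numbers were 0.71 to 0.96 times those reading through the start of the tRNA listed next. The remaining 701 positions were analysed. In the treated and control libraries 82.1% to 98.3% of coverage counts were even, as when both mates of a pair are counted, but in the enzyme libraries only 58.7% to 59.9% were. Counts were divided by 2 before Wilson 95% intervals were computed, and in the enzyme libraries this is a cautious choice that widens the intervals. These intervals cover counting error only. The last 16 or more listed positions of each tRNA had no stops, and the shortest read at a stop was 20 bases in 7 of the 9 sequences. Among the 701 positions, 530 had a stop in at least 1 of the 8 treated and control libraries, and 171 had none.

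The target site was position 37, the base 3′ of the anticodon, found from the anticodon stem and loop of each listed sequence. Of the offsets -1, 0 and +1, the offset 0 had the highest mean stop rate over all libraries (77.0%) and was used for all tRNAs. The listed sequence of Leu(UAA) carries AAA at the anticodon, against TAA from its label. Positions are those of the listed sequence unless called canonical.

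Stop rates were compared between treated and control on the logit scale, with 0.5 added to stops and to reads without a stop, at positions with at least 20 reads in each library. limma 3.58.1 in R 4.3.3 (lmFit and eBayes) gave two-sided tests, with Benjamini-Hochberg adjustment over the 701 positions and a threshold of 0.05. Differences are given as odds ratios of a stop with 95% confidence intervals. The mean over tRNAs was compared with a two-sided exact permutation test over 70 splits, whose smallest p is 0.0286. Other calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots matplotlib 3.10.9. On simulated data built from 529 positions, the limma test called 4 of 100 positions with a 2-fold change in odds and 53 of 100 with a 4-fold change. It also called 3 of 329 unchanged positions. The simulation gave all positions the same residual SD of 0.611 in logit and independent libraries. It therefore does not give the power at the target sites, whose own spread was not modelled, or the false calls under paired or similar libraries.

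Replicates 3 and 4 were closer to each other than other pairs (chi-square per degree of freedom 9.39 in treated and 2.57 in control, against 182 to 676 elsewhere). They still differed beyond sampling noise and were kept apart. Deviations from the group means correlated between libraries of the same number (0.22, 0.37, 0.36 and 0.39 for numbers 1 to 4), so the numbers were taken to pair the samples. Treated replicate 3 correlated more with control replicate 4 (0.41) than with control replicate 3, and treated replicate 4 more with control replicate 3 (0.40) than with control replicate 4.

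Designs, lists and most alternatives were fixed before the data were examined. The alternatives were the coverage minimum, each library left out, blocks for the replicate number and for the pair of replicates of a peak list, each such pair alone, the neighbouring offsets, untransformed rates, a quasi-binomial model, a constant of 5, the median over tRNAs and summed counts. Averaging replicates 3 and 4, keeping only positions with a stop, and centring each library on its median were added after seeing the data. The naming rule covered each target site, up to 5 positions with the lowest adjusted p in each direction, up to 3 examples of position 8, and the 10 highest-scoring peaks of each list. Without scores the last part named none. Genes were taken from the RefSeq annotation of assembly ASM584v2, whose sequence name matches that of the peak lists.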

Results

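Reverse transcription stops were counted along 9 tRNA sequences that carry ms2i6A at position 37, a hypermodified adenosine next to the anticodon. The 4 treated libraries held between 1312670 and 2004660 stops on these tRNAs, and the 4 controls between 645850 and 940410. The 3 enzyme libraries were deeper, with 44763896 to 48273131 stops. Coverage at the target sites was lowest in control replicate 2, at 1692 reads for Phe(GAA).

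The first comparison asked whether the ReACT treatment changed the stop rate at known ms2i6A sites. Position 37 stopped reverse transcription strongly in both groups. In Leu(CAA) the stop rate was 88.5% ± 0.681 (SD, n = 4) in treated and 88.1% ± 2.54 (SD, n = 4) in control libraries. Phe(GAA) was the 1 target site of 9 that passed the threshold, rising from 49.0% ± 4.10 to 70.9% ± 2.70 (SD, n = 4 each). Its odds ratio was 2.53 (95% interval 1.55 to 4.14, limma adjusted p = 0.0138), with each treated library above each control. Adjusted over the list alone, 1 of the 9 sites passed as well (limma adjusted p = 0.0180).

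The other 8 target sites did not pass, with or without the replicate number as a block. Leu(UAA) and Ser(CGA) were nonetheless higher in treated libraries in 4 of 4 pairs, by 4.78 to 26.7 and 3.24 to 24.1 percentage points, with limma adjusted p of 0.0975 and 0.122 under the block. Trp(CCA) stood at 79.9% ± 1.54 in treated and 83.01% ± 3.37 in control libraries, with an odds ratio of 0.803 (0.483 to 1.33), and was lower in treated libraries in 3 of 4 pairs, by 4.07 to 4.76 percentage points. Leu(UAA) stood at 82.0% ± 2.10 and 71.3% ± 11.7, with an odds ratio of 1.77 (0.892 to 3.50, limma adjusted p = 0.165). Ser(CGA) stood at 58.7% ± 5.04 and 46.9% ± 12.9, and Cys(GCA) at 68.1% ± 5.99 and 61.1% ± 14.6. For Ser(UGA) the values were 78.6% ± 1.28 and 77.6% ± 1.89, for Tyr(GUA) 81.9% ± 0.388 and 77.5% ± 6.005, and for Tyr2(GUA) 80.9% ± 0.983 and 77.7% ± 5.98. By exact permutation, Phe(GAA) and Leu(UAA) each reached the smallest p of 0.0286, or 0.129 after adjustment over the 9 sites. The Phe(GAA) call was lost without treated replicate 3 (limma adjusted p = 0.0503), without treated replicate 4 (0.0545), with replicates 3 and 4 averaged (0.134) and with replicates 1 and 2 alone (0.571), within a range of 0.00123 to 0.571 over the alternatives. Its odds ratio under these 4 settings was 2.55, 2.46, 2.45 and 2.29, against 2.53 with all libraries, while the standard error of its log odds was 0.271, 0.264, 0.344 and 0.675, against 0.217. Centring each library on its median lowered the log odds at each position by 1.18, so sites that rose by less turned negative. Relative to that median, Phe(GAA) stood at -0.25 (limma adjusted p = 0.567), and Leu(CAA), Ser(UGA) and Trp(CCA) were called lower.

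**Figure D1:**
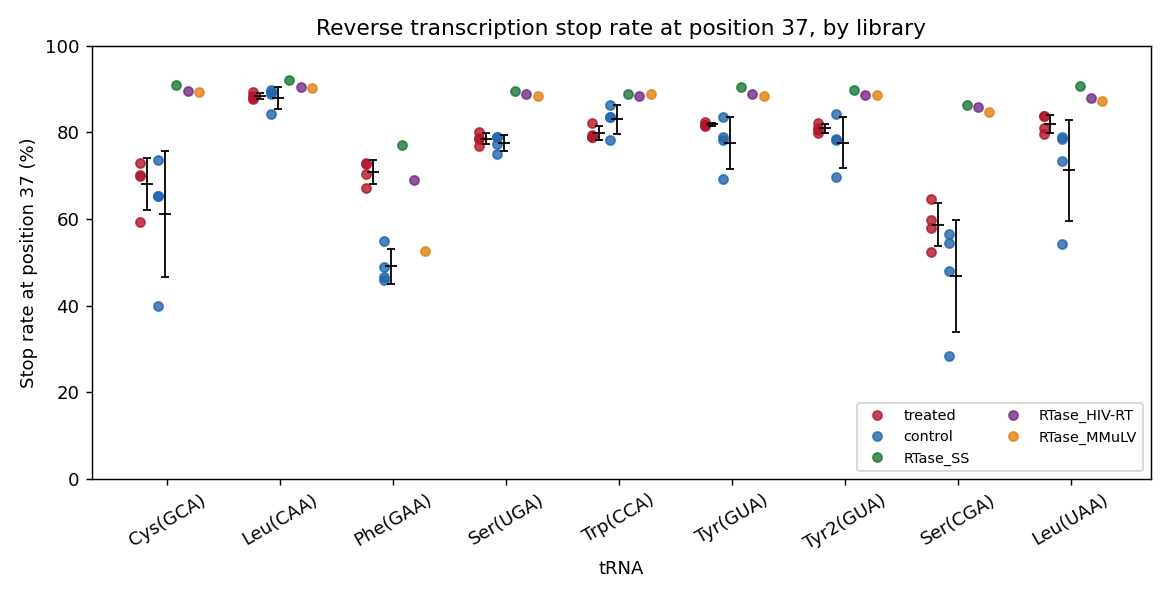
Stop rate at position 37 (%, vertical axis) in each library for each tRNA (horizontal axis), with points for single libraries and black bars for the mean ± SD of the 4 treated and 4 control libraries. Treated and control libraries are fully apart in Phe(GAA), at 70.9% and 49.0% on average, and narrowly in Leu(UAA), where the lowest treated library is at 79.5% and the highest control at 79.0%, while in Leu(CAA) they overlap at 88.5% and 88.1%.

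Averaged over the 9 sequences, the target stop rate was 76.6% ± 0.959 in treated and 70.2% ± 5.79 in control libraries (SD, n = 4 each). The difference of 6.35 percentage points reached the smallest p that the exact permutation test allows (p = 0.0286). It was uneven over the tRNAs and does not show a rise at each site. Phe(GAA) rose by 18.2 to 24.6 points in the 4 pairs. In pairs 3 and 4 the next largest differences, in Leu(UAA), were 4.78 and 5.19 points. Leu(UAA) and Ser(CGA) were higher in treated libraries in 4 of 4 pairs, and Cys(GCA), Tyr(GUA) and Tyr2(GUA) in 3 of 4. Leu(CAA), Ser(UGA) and Trp(CCA) were higher in 1 of 4, pair 1. Control replicate 1 had the lowest mean, at 61.6%, and without it the difference was 3.46 points. With the replicate number as a block the exact sign-flip p was 0.125, the smallest that 4 pairs allow, and with stops and coverage summed over tRNAs the difference was 3.19 points (exact permutation p = 0.4). As a median over the 9 sequences it was 3.58 points (exact permutation p = 0.0286).

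The scan of positions asked whether stops also moved elsewhere in the same tRNAs. Among the 530 positions with a stop in the 8 libraries, 195 rose and 3 fell in treated libraries (limma, adjusted over 701 positions). The median odds ratio over the 530 positions was 2.88. Further than 5 bases 5′ of position 37 the median was 3.75, with 127 of 275 positions higher, and further than 5 bases 3′ it was 2.96, with 43 of 156 higher. Within 5 bases it was 1.64 on the 5′ side and 1.76 on the 3′ side, and at position 37 it was 1.28, with 1 of 9 higher. This order holds for odds but not for percentage points averaged over the libraries. Stop rates at position 37 also start far higher. In percentage points, the median stop rate per library was on average higher in treated libraries by 3.58 at position 37. Further 5′ the difference was 1.79 points and further 3′ it was 0.501 points. By base, the median odds ratio outside position 37 was 5.93 at A, 3.57 at G, 2.41 at C and 1.79 at T.

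The 5 positions with the lowest adjusted p were Ser(UGA) 8 and 4, Leu(CAA) 8, Trp(CCA) 9 and Tyr(GUA) 9, each with a limma adjusted p of 0.000404. Tyr(GUA) 9 rose from 1.62% ± 0.808 to 25.5% ± 5.88 (SD, n = 4 each), with an odds ratio of 21.8 (11.2 to 42.6). Trp(CCA) 9 rose from 0.697% ± 0.111 to 6.51% ± 0.874, and Ser(UGA) 4 from 0.560% ± 0.207 to 7.62% ± 1.28. Cys(GCA) held the 3 positions that fell, at 18, 16 and 20 in the D loop. Cys(GCA) 18 fell from 8.66% ± 2.43 to 2.25% ± 0.706, with an odds ratio of 0.240 (0.123 to 0.466, limma adjusted p = 0.00813). A further 16 positions passed as lower without a stop in any of the 8 libraries, among them Phe(GAA) 57, 58, 59 and 60, and carry no fold.

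The count of higher positions was 112 without treated replicate 3, 107 without treated replicate 4, 66 with replicates 3 and 4 averaged, and 0 by limma with replicates 1 and 2 alone, where 112 positions had an unadjusted p under 0.05. Centred on each library's median, 39 positions were higher and 43 lower, and with the replicate number as a block 253 were higher and 6 lower among the positions with a stop (54 lower with those without a stop, against 19). The 3 lower positions became 1 without treated replicate 1, 3 or 4 or control replicate 3 or 4, 6 without treated replicate 2 and 5 without control replicate 2.

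**Figure D2:**
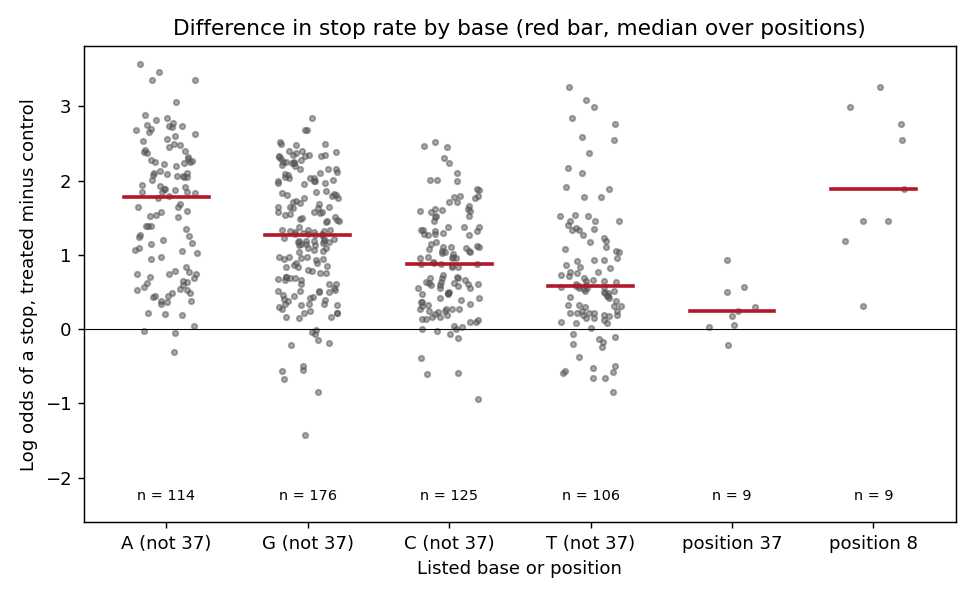
Difference in log odds of a stop, treated minus control (vertical axis), at each of the 530 positions with a stop, grouped by listed base outside position 37, and for position 37 and position 8 (whose points are also among the T positions). The red bars are medians, highest for A among the bases at 1.78 and at 0.25 for position 37.

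Position 8, a 4-thiouridine in many E. coli tRNAs and so another sulfur-containing site, rose in 8 of 9 sequences, and in 8 of 9 when adjusted over the list alone. Leu(CAA) 8 rose from 0.366% ± 0.188 to 8.04% ± 1.67 (SD, n = 4 each), with an odds ratio of 25.9 (12.8 to 52.4). Ser(UGA) 8 rose from 0.165% ± 0.0663 to 3.19% ± 0.948, and Tyr(GUA) 8 from 1.46% ± 0.9895 to 17.2% ± 3.69. Cys(GCA) 8 stood at 8.50% ± 1.87 and 11.3% ± 2.202 and did not pass (limma adjusted p = 0.315). The mean over the 9 sequences was 2.01% ± 0.211 in control and 8.73% ± 1.12 in treated libraries (exact permutation p = 0.0286). With the replicate numbers as pairs the exact sign-flip p was 0.125, the smallest that 4 pairs allow. With each library centred, 4 of the 9 were called higher, with replicates 3 and 4 averaged 5 were, and with replicates 1 and 2 alone 0 were called by limma, against 6 at an unadjusted p under 0.05.

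**Figure D3:**
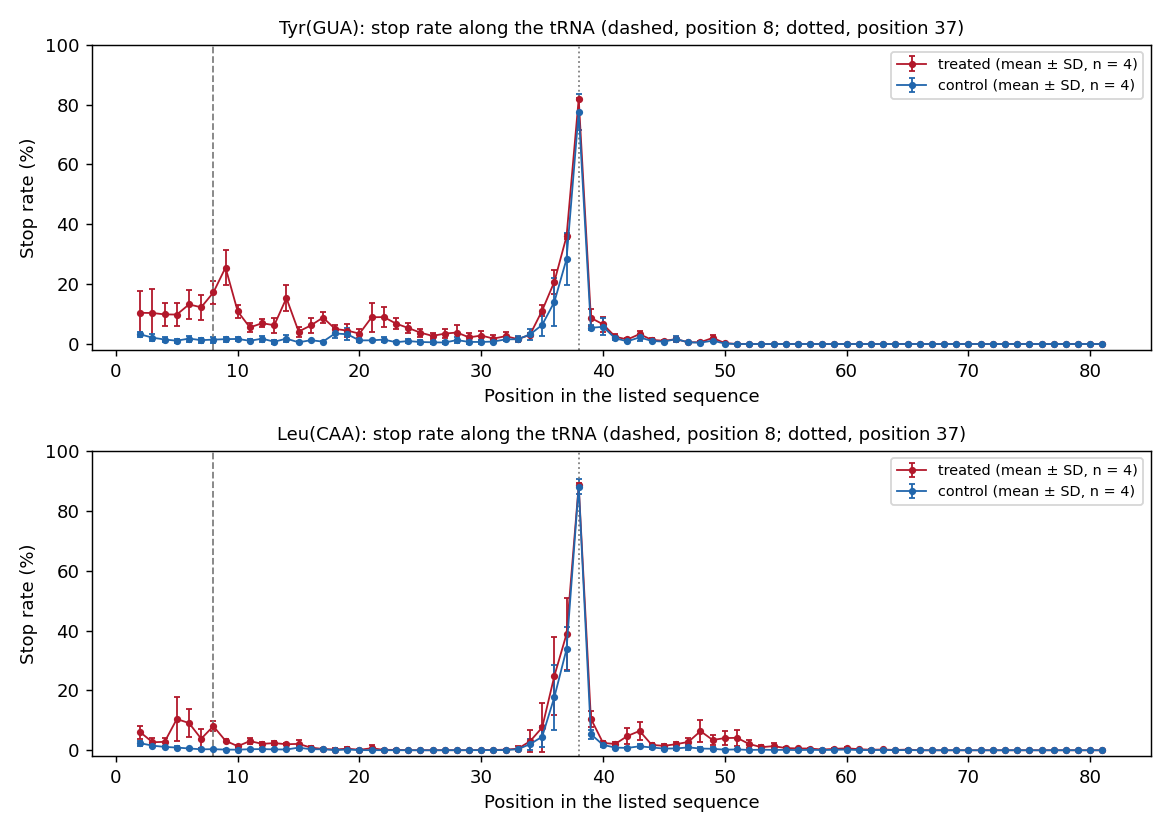
Stop rate (%, vertical axis) along the listed sequences of Tyr(GUA) and Leu(CAA) (horizontal axis), as mean ± SD of the 4 treated and 4 control libraries. Both groups peak at position 37 (listed position 38), and the treated libraries are higher at position 8, at 17.2% against 1.46% in Tyr(GUA) and 8.04% against 0.366% in Leu(CAA).

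Fewer sites than at position 8 passed at the other positions listed as modified. Over the 530 positions with a stop 36.8% were higher, and 31.1% within 5 bases 5′ of position 37, so these small counts do not set the listed positions apart. At canonical position 32, 4 of 9 sites rose, with group means of 0.903% in control and 2.14% in treated libraries (exact permutation p = 0.0286, without the pairing). At canonical position 34, 2 of 9 rose (exact permutation p = 0.143 for the mean), and at canonical position 39, 1 of 9 rose (exact permutation p = 0.171 for the mean). Adjusted over the list alone the counts were also 4, 2 and 1. Positions 46 and 47, the sites of m7G and acp3U in some tRNAs, were read in Phe(GAA) and Trp(CCA), and 0 of 2 sites passed at each by limma, in the full scan, over the list alone and at an unadjusted p under 0.05. Phe(GAA) 46 stood at 35.2% in treated and 39.9% in control libraries and Phe(GAA) 47 at 73.0% and 68.9%, while Trp(CCA) 46 stood at 0.504% and 0.426% and Trp(CCA) 47 at 0.525% and 0.382%.

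The target site had the highest stop rate of its tRNA in 90 of 99 pairs of library and tRNA. This count is partly fixed by the choice of target, since the offset from position 37 was the one with the highest mean stop rate in the same libraries. Phe(GAA) accounted for the 9 exceptions, where position 47 was highest. In treated replicate 2, for example, position 47 of Phe(GAA) reached 84.3% and position 37 reached 67.2%.

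The enzyme libraries asked whether the reverse transcriptase changes the stop rate. There is 1 library per enzyme, so only these libraries can be compared. The mean target stop rate was 88.4% with Superscript III, 86.4% with HIV reverse transcriptase and 84.3% with MMuLV reverse transcriptase. Phe(GAA) differed most between them, at 77.1% (95% Wilson interval 76.5 to 77.7), 69.1% (68.4 to 69.8) and 52.6% (51.8 to 53.4) in that order. In the other 8 sequences the enzymes lay within 3.50 percentage points of each other.

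The peak lists held 59 peaks for treated replicates 1 and 2 and 54 for replicates 3 and 4. Of the first list, 35 peaks shared at least 1 base with the second, and 37 of the second with the first. tRNA genes were covered by 39 and 28 peaks, ncRNA or tmRNA genes by 10 and 18, protein-coding genes by 6 and 8, and rRNA genes alone by 4 and 0. Counting a gene as covered from 1 shared base, 9 of the 11 genes for the known ms2i6A tRNAs (81.8%) were covered in the first list and 7 (63.6%) in the second. Of the 75 other tRNA genes, 56 (74.7%) and 25 (33.3%) were covered, and no difference was detected with this number of genes (Fisher's exact p = 1.0 and 0.0912, two-sided). Both tests treat genes as independent, although a single peak of the first list could cover 4 neighbouring genes, so their p-values are only a rough guide. The overlap was as short as 9.2% of a gene for lysV in the first list, named after the lists were seen. For example, leuX (4496405 to 4496489) was covered in both lists, while pheV (3110366 to 3110441) and pheU (4362551 to 4362626) were covered in neither. Since read filtering is not given, the lack of a peak does not show that a tRNA was not enriched. Of the genes for tRNAs with A37 but without ms2i6A, selC (3836222 to 3836316), the selenocysteine tRNA, was covered in both lists, serX (1097565 to 1097652) in the first alone, and serW in neither.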

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

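The tests of explanations in this part were chosen after the results were seen. Of 40 groups of 4 libraries examined, 3 had a library far from the other 3, and chance gives about 2.0 (5% of groups). All 3 were control replicate 1. Its Tyr(GUA) 9 stop rate was 2.83%, against 1.12% to 1.27% in the other controls. Its Cys(GCA) 20 stop rate was 6.33%, against 10.03% to 10.5%.

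Its mean stop rate over the 9 target sites was 61.6%, against 72.8% to 73.6% in the other controls, and it was the lowest control in 8 of 9 tRNAs. A treated library with the wrong label is argued against, because its mean position 8 stop rate was 2.30%, below the lowest treated library at 7.22%. Counting error is argued against as well, since its widest Wilson interval spanned 3.07 percentage points and its gap to the next control was 11.2 points. A batch shared by samples with number 1 stays open: treated replicate 1 was also the lowest of its group, but only by 1.65 points. No biological explanation was tested, since the labels give none. Control replicate 2 was not flagged but stood apart in background stops. Its median 5′ stop rate was 0.218%, against 0.704% to 0.802% in the other controls. Of the 530 positions, 58 had no stop in control replicate 2, against 4 to 8 in the other controls. Without control replicate 2, 234 positions were higher, against 195 with all libraries.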

How the results depend on the processing

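Removing or raising the coverage minimum changed nothing, since no position had fewer than 200 reads. Over the leave-one-out fits, called target sites ranged from 0 to 1, higher positions from 107 to 234, lower positions from 1 to 53, lower positions with a stop from 1 to 6 and position 8 sites from 7 to 8. The mean target difference ranged from 3.46 to 7.46 points, with an exact permutation p of 0.0571, the smallest that 3 against 4 allow. In the order target sites, higher, lower, lower with a stop and position 8 (main values 1, 195, 19, 3 and 8), replicates 1 and 2 alone gave 0, 0, 0, 0 and 0, replicates 3 and 4 alone 3, 402, 101, 23 and 8, averaging replicates 3 and 4 gave 0, 66, 0, 0 and 5, and centring gave 3, 39, 43, 43 and 4. With replicates 1 and 2 alone limma called 0 positions, against 112 at an unadjusted p under 0.05. Lower positions were 54 with the replicate number as a block (6 with a stop), 50 with the block for pairs of peak lists (4 with a stop), 4 with untransformed rates, 4 with the quasi-binomial model and 3 with only positions with a stop. The replicate block changed no other call among target sites and position 8. The 3 target sites called with replicates 3 and 4 alone were Phe(GAA) and Leu(UAA), higher, and Trp(CCA), lower (odds ratio 0.746). Replicates 3 and 4 lay closer together than other pairs (SD of the logit difference 0.217 in treated and 0.235 in control, against at least 0.599). Calls from them alone therefore rest on a narrow spread and may overstate certainty. At offsets -1 and +1, 3 and 2 sites were called. The mean difference was 6.35 points with either block (exact p = 0.125 and 0.0556), 8.68 and 4.02 for replicates 1 and 2 or 3 and 4 alone, 7.13 with replicates 3 and 4 averaged and 3.19 with summed counts. Of these, the summed counts alone could reach 0.05 in their test (exact permutation p = 0.4). As a median over tRNAs the difference was 3.58 points, and at offsets -1 and +1 it was 7.98 and 3.63, each with an exact permutation p of 0.0286. Centring lowered the log odds at each position by 1.18, which by itself turned them to -1.15 for Leu(CAA) and -1.12 for Ser(UGA), which gained a call, and -0.25 for Phe(GAA), which lost it. Enzyme means moved to 89.7%, 88.7% and 88.3% as medians, to 52.7%, 50.8% and 48.8% at offset -1, and to 5.70%, 7.84% and 7.08% at offset +1 (Superscript III, HIV and MMuLV). Peak overlap was 29 of 59 with a reciprocal overlap of 50%, and a stricter discovery rate could not be run without a score. Over named single sites and alternatives, 296 combinations were called in both, 175 in neither, 72 lost the call and 5 gained one. Apart from centring, the cause of these changes was not tested. The lowest target site coverage was 1692 reads, at Phe(GAA) in control replicate 2. In treated replicate 4 the lowest was 3336 reads, at Ser(CGA). Each target site had at least 30886 reads in the enzyme libraries.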

Other observations

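The tests of explanations in this part were chosen after the results were seen. Their exact permutation tests do not use the pairing of replicate numbers, and a paired test of 4 pairs cannot go below 0.125. Position 9 rose as well as position 8, in 6 of 9 sequences (8 of 9 adjusted over the list alone), from a mean of 1.84% ± 0.235 in control to 9.28% ± 1.06 in treated libraries (SD, n = 4 each; exact permutation p = 0.0286). Its median odds ratio was 11.9, against 6.63 at position 8. In the labelled libraries without enrichment, stop rates were higher than in the treated and control means at each canonical position from 31 to 37. With Superscript III they went from 3.03% at position 31 over 38.4% at position 34 to 52.7% at position 36, against 1.11%, 8.48% and 32.4% in treated and 0.560%, 5.55% and 24.4% in control libraries. Among peaks outside tRNA genes, named after seeing the lists, small RNA genes such as cyaR, gcvB and rprA and the 6S RNA gene ssrS were in both lists.

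The broad rise of stop rates in treated libraries was set against other groupings of the 8 libraries. The replicate numbers were taken to pair the samples, from correlations in these same data that did not tell numbers 3 and 4 apart. The real split was therefore compared with the 8 splits, itself included, that part all 4 pairs, which are too few for a share under 0.05. The real split gave 214 called positions by limma, 1 called target site and 8 called position 8 sites, and the highest of the others gave 0 of each (at an unadjusted p under 0.05, 331 positions against at most 62). The other 27 of the 35 splits put at least 1 pair on the same side, and they also gave 0 called positions by limma, with at most 122 at an unadjusted p under 0.05. Low counts alone are argued against, since the median log odds difference was 0.68 over 295 positions with at least 20 stops in each library (exact permutation p = 0.0286), although this is below the 1.06 over all 530. A background of fragment ends alike for every base is argued against, since the A minus T difference in median stop rate was 2.89 percentage points higher in treated libraries (exact permutation p = 0.0286). The A and T positions were not matched for their part of the tRNA. Fragment ends that favour certain bases were not tested. The labelling step alone, without enrichment, cannot be told apart: the highest median 5′ stop rate of the 3 labelled libraries was 1.14%, below the lowest treated library at 2.11%, but enzyme and depth differ too.

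The rise at position 8 may be more than part of the broad rise. Its lead over other T positions of the 5′ part was 1.17 log odds higher in treated libraries (exact permutation p = 0.0286), with tRNAs ranging from 0.079 in Tyr2(GUA) to 2.83 in Leu(CAA). T was the base with the lowest median odds ratio outside position 37, at 1.79, against 5.93 at A. Over all positions further 5′ it was 3.75, against 6.63 at position 8, so the lead over T need not hold over other bases. In Cys(GCA) the lead was 0.963, although position 8 did not pass (log odds 0.316) and the T at position 20 fell (-0.848). Position 8 was not tested against position 9, whose median odds ratio was higher, so the lead does not single out position 8. In Tyr(GUA), position 9 is itself a T that rose (odds ratio 21.8) and was among the other T positions compared. A candidate explanation is a reaction at position 8 in the labelling step, and it stays open. The lowest mean position 8 stop rate in the 3 labelled libraries without enrichment was 5.90%, above the highest control at 2.30%, but the tRNAs differed. In all 3 libraries, 5 of 9 lay above the highest control and 3 (Cys(GCA), Phe(GAA) and Leu(UAA)) below the control mean. Of the 5, Tyr(GUA) and Tyr2(GUA) had the highest rates in percent, while Leu(CAA) had 6.70% to 12.3% against at most 0.590% in control libraries. The lead over other T positions, a measure required only after both sets of values were seen, was 1.52 log odds with Superscript III and 1.20 with MMuLV reverse transcriptase, above the control range of 0.55 to 0.90, and 0.86 with HIV reverse transcriptase, within it.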
